A study of Homo sapiens with 9 samples.

How the data were processed

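Human cord-blood CD34+ hematopoietic stem and progenitor cells (HSPCs) were cultured for 28 days with cytokines and growth factors, and with TCDD, a dioxin that binds the aryl hydrocarbon receptor (AHR), at 1 nM or with its DMSO vehicle. Per the labels, cells were harvested untreated at day 0 and from each arm at days 7, 14, 21 and 28, with 1 library per group and wells pooled within a library. Single-cell libraries were made with 10x Genomics 3′ chemistry and sequenced on an Illumina HiSeq.

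The deposited values were counts of unique molecular identifiers (UMIs) per gene and cell barcode, in 1 matrix for each of the 9 libraries. The submitters' processing notes name Cell Ranger 2.1 and GRCh38, while the matrices' own headers name Cell Ranger 3.1.0, so which version made the counts is open. No normalization is recorded for these deposited counts, and the lowest deposited barcodes held about 500 UMIs (500 to 518 per library). The matrices hold 33538 genes, of which 33456 matched the identifiers of GENCODE release 29 on GRCh38, and 24 symbols were duplicated. Coordinates below come from that annotation. Whether the counting used strand or joined overlapping genes is not given in the sources used here, so genes that overlap another gene or have a near-identical paralog are uncertain in level.

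Cells with at least 500 detected genes and at most 20% mitochondrial counts were kept, 28893 of 31068 barcodes. Kept cells numbered 567 at day 0. The vehicle libraries kept 4064, 4311, 3368 and 5553 cells at days 7, 14, 21 and 28, and the TCDD libraries 4793, 1978, 1947 and 2312. Total counts of the deposited barcodes ranged from 9554011 at day 0 to 131173917 in the vehicle day 7 library. Doublets were left in, and in 1 alternative the cells with the highest Scrublet scores were removed at 0.8% per 1000 cells, which took 0.53% to 4.45% of cells. Sex-linked genes (102) were left out of every step. A comparison for mixed-up samples by sex-linked genes is not reported here.

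Counts of kept cells were summed per library. The treatment effect was tested with edgeR 4.0.16 (TMM normalization, filterByExpr, glmQLFit and glmQLFTest, two-sided) with harvest day as a block. This leaves 3 residual degrees of freedom, and the spread is that of the TCDD minus vehicle difference between days, which may hold time courses as well as chance. The trend over days (slope per 7 days, adjusted for treatment) and the change of the treatment effect with day (2 residual degrees of freedom) were fitted on the same 8 cultured libraries. Benjamini-Hochberg adjusted p below 0.05 was the threshold. Single days and day 0 had no test: values are CPM, the deposited counts scaled to the library total, with exact 95% Poisson intervals, and log2 ratios with 1 CPM added. Shares of cells carry exact Clopper-Pearson intervals, and a count of 0 allows up to 3 counts of the total. All such intervals cover counting error only. Agreement between days was described by correlation across genes of at least 10 CPM, without p-values.

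Gene lists (31: 16 responses and 15 cell types), cell type markers, tests, named genes and most alternatives were fixed before the data were examined. Lists were tested on the edgeR fit with camera of limma 3.58.1 (preset correlation 0.01), with camera using an estimated correlation, and with fry, adjusted over lists. On a single day, a list's median was placed as a percentile among 10000 random lists of the same size matched on expression. Cell types overlap in these markers: several markers of 1 type are expressed in another, and the MHC class II genes mark dendritic cells, monocytes and B cells together.

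The named-gene rule took the 12 largest changes in each direction that passed and kept 1 sign on all 4 days at 10 CPM or more, filled by smallest p where fewer passed. It took the 8 largest trends in each direction at 50 CPM or more, the 5 smallest p of the interaction, and the 5 highest and 5 lowest single-day ratios with 100 CPM or more in the higher library. It also took up to 5 genes in each direction per cell class at 20 CPM or more, all tested members of the AHR target and AHR complex lists, and up to 4 members of every other list by p. Never named were sex-linked, mitochondrial and ribosomal protein genes, genes with common whole-gene deletions, and clone-based names. Some genes that the rule took are not reported here.

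Cells were clustered in scanpy 1.11.5 with 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1.2 (leidenalg 0.10.2, igraph 0.11.9), without AHR target, mitochondrial, ribosomal or sex-linked genes. Of 40 clusters, 29 were named "X-like" from the fixed markers by scoring thresholds that were set after seeing the data, and the others keep their number. Class shares were tested with edgeR on cell numbers with the day block. Within a class, counts were summed and tested where at least 3 days had 50 cells in both libraries.

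On data simulated from these libraries' means and sizes over 17344 genes, the treatment test found 82 of 100 genes changed by 1 log2 unit and 95 of 100 changed by 2, with 16 false calls. The trend test found 63 and 96 of 100, with 4 false calls. The share test found all 30 of the 4-fold changes simulated over 10 sets of 23 classes, with 2 false calls. Each simulated gene had a dispersion of 0.0328 and each simulated class one of 0.05, with no differences between days. These counts hold for those settings and do not give the power of the tests on the real libraries.

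Alternatives covered RLE normalization, no low-count filter, DESeq2 1.42.0, limma-voom, all barcodes, a stricter cell filter (1000 genes, 10% mitochondrial), doublet removal, each day left out in turn, no day block and cells thinned to 1500 counts. Between 1 cell at day 0 and 349 cells in the vehicle day 28 library were too shallow for the thinning. Others used log2 of the day, the vehicle libraries alone with and without day 0, a pseudocount of 5 CPM, genes of at least 50 CPM, Leiden resolutions 0.6 and 2, clustering with the AHR genes kept, classes by highest marker score, TMM on class counts and an exact sign-flip test over days. Alternatives added after seeing the data gave the TCDD libraries of days 14 to 28 a term of their own, which leaves the treatment effect to day 7, left out read-through or overlapping genes, and left out early clusters of the TCDD day 21 library. Analyses used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.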

Results

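Gene expression was measured in single cells of a human culture in which cord-blood CD34+ HSPCs form blood cells over 28 days, with vehicle or with TCDD, a potent AHR ligand. The series asks what role the AHR has in this model of blood formation. There were 9 libraries, 1 per group: untreated day 0, and vehicle and TCDD at days 7, 14, 21 and 28. No group was replicated, so a test across the 4 days asks whether a difference held over days, and no single day has a test. Median counts per kept cell were 14824 at day 0. In the vehicle libraries they were 29388 at day 7, 18652 at day 14, 16651 at day 21 and 10260 at day 28, and in the TCDD libraries 23646, 32535, 24724 and 23067. On days 14, 21 and 28 the TCDD libraries thus held fewer cells at more counts per cell than vehicle.

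The first comparison describes the culture itself. Day 0 cells were almost all HSPC-like (94.4% of 567 cells, interval 92.1% to 96.1%). By vehicle day 7 that share was 6.59%, with other clusters holding the class: cluster 25 at day 0, clusters 1 and 20 later. PRTN3 and ELANE, proteases of neutrophil granules, were at 1.21 and 1.43 CPM at day 0 and at 3294 and 1696 CPM at vehicle day 7. The alarmins S100A8 (4.17 to 1255 CPM) and S100A9 (10.97 to 2142 CPM) and the globin HBB (7.02 to 1506 CPM) went the same way. Lower at day 7 were the immediate early genes JUN (1065 to 13.1 CPM) and FOSB (325 to 6.93 CPM), the growth factor AREG (418 to 7.12 CPM) and AVP, a marker of primitive HSPCs (175 to 3.22 CPM). All Poisson intervals of these pairs were apart, and none has a replicate check.

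From day 7 to day 28, macrophage genes and some neutrophil genes rose, and progenitor granule, eosinophil, cell cycle and sterol genes fell. The trend test called 3279 of 16823 genes up and 3226 down (edgeR). Among the largest were APOE and APOC1, apolipoproteins of macrophages, with slopes of +2.78 (SE 0.255, adjusted p = 0.000561) and +1.85 log2 per 7 days, GPNMB (+2.49) and the sterol hydroxylase CYP27A1 (+1.77). CAMP, an antimicrobial peptide of neutrophil granules (+3.13, SE 0.594, adjusted p = 0.00582), MMP9 (+3.08), the stress regulator NUPR1 (+2.83) and the tetraspanin CD9 (+1.93) also rose. The primary granule genes ELANE (−1.42), PRTN3 (−1.30), AZU1 (−0.95) and CTSG (−0.70) fell, as did THBS1, PRSS57, CST7 and NPW (−0.95 to −0.72). Left-out days moved these counts: without day 7 the test called 1557 up and 1660 down, and without day 28 it called 988 and 1145. The vehicle libraries alone gave 798 and 846, and with day 0 added 3 and 0.

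By list, 12 of 13 macrophage markers rose (CHIT1 +3.75, C1QC +1.69), as did 14 of 15 lysosome genes (PSAP +0.95, NPC2 +0.59), 6 of 12 neutrophil markers (FCGR3B +3.20), 8 of 14 B lineage markers and 9 of 18 type I interferon genes, and no falling member of these lists passed. Adjusted over the list alone the counts were 12, 14, 6, 8 and 9. Of 7 eosinophil markers 6 fell (EPX −2.62, IL5RA −1.43), and 6 adjusted over the list alone. In the vehicle libraries macrophage-like cells went from 0.0738% on day 7 to 15.3% on day 28, and neutrophil-like cells from 0.0492% to 21.6%. All 18 cholesterol synthesis genes fell (SQLE −1.08, ACAT2 −0.62, FDPS −0.51), as did all 18 G2/M genes (CDC20 −0.61, PLK1 −0.58) and 17 of 18 S phase genes (GINS2 −0.63, CDC6 −0.56). Adjusted over the list alone these were 18, 18 and 18. Glycolysis genes went both ways: 11 of 14 fell (GAPDH −0.33, ENO1 −0.33) and 2 rose, with the same counts adjusted over the list alone.

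The treatment comparison asks which genes differed between TCDD and vehicle over the days. CYP1B1, a xenobiotic-metabolizing enzyme and classical AHR target on chromosome 2 (GRCh38, 38066973 to 38109902, minus strand), was higher with TCDD on 4 of 4 days. It stood at 132 CPM with vehicle and 510 CPM with TCDD on day 7, 38.9 and 222 on day 14, 51.1 and 155 on day 21, and 99.1 and 213 on day 28, against 0.33 CPM at day 0. The model gave +1.81 log2 (SE 0.219, adjusted p = 0.128), which did not pass, and CYP1B1 overlaps another annotated gene on its strand. Over its alternatives the adjusted p of CYP1B1 ranged from 2.3e-15 with DESeq2 to 1 without the day block, and it passed with cells thinned (0.00725) and with no low-count filter (0.0437). NQO1, a quinone reductase, was higher on 4 of 4 days (+1.05, SE 0.162, adjusted p = 0.144), as was AHRR, the AHR repressor (+0.69, SE 0.201, adjusted p = 0.268). The AHRR ratio shrank from +1.38 at day 7 to +0.74, +0.21 and +0.23. TIPARP, another feedback regulator, had +1.28, +0.85, +0.32 and −0.17, and SERPINB2 +1.43, +1.62, +0.22 and −0.13. SLC7A5 (−0.38), EREG (+0.23) and STC2 (+0.10) had no shared direction over days. CYP1A1, the best known AHR target, was near the floor: 68 counts (0.527 CPM) at TCDD day 7 against 6 (0.0460 CPM) with vehicle, and at most 8 counts elsewhere, with 0 in the TCDD day 21 library.

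**Figure D1:**
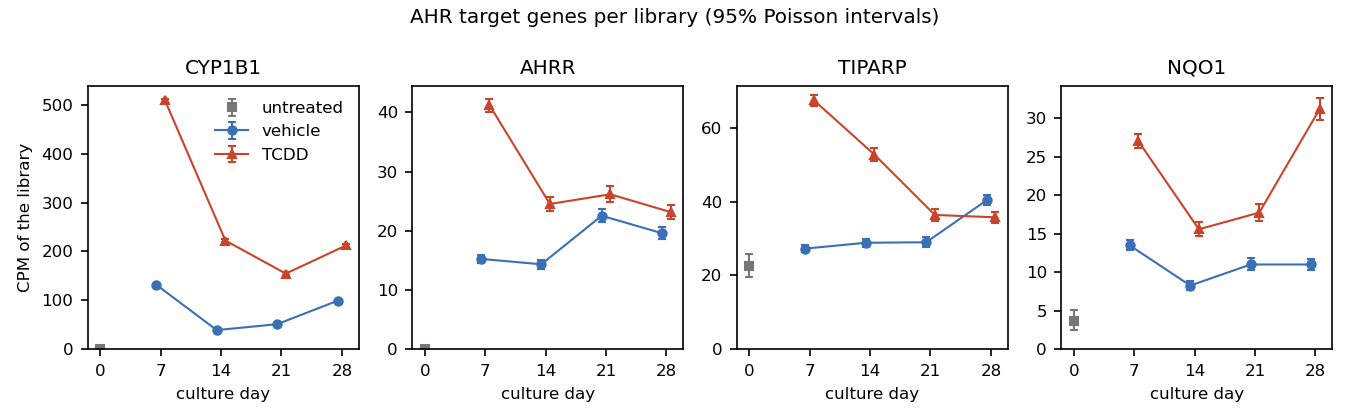
CPM of CYP1B1, AHRR, TIPARP and NQO1 (y axis, each from 0) by culture day (x axis) in the 9 libraries, with 95% Poisson intervals. CYP1B1 and NQO1 lay above vehicle in the TCDD library on 4 of 4 days, while TIPARP was lower with TCDD on day 28.

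As a set, the AHR target genes, 8 of 12 of which were measured well enough to test, were called higher (median +0.65; camera adjusted p = 2.1e-07), a call lost with an estimated correlation (adjusted p = 0.176) and with fry (adjusted p = 0.0974). No member passed over all genes and 3 passed adjusted over the list alone. Their single-day median went from +1.11 on day 7 to +0.79, +0.27 and +0.05, at percentiles 100, 100, 99.75 and 95.06 of matched random lists. The receptor complex itself was not called (camera adjusted p = 0.454; 0 of 7 by either adjustment). AHR was at −0.13, HSP90AA1 +0.13, ARNT +0.11, PTGES3 +0.10, HSP90AB1 +0.04 and NCOA1 −0.02. AHR had ratios of +0.21, +0.23 and +0.10 on days 7 to 21 and −1.14 on day 28.

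Beyond the AHR targets, genes such as MMP2 and ACP5 were higher with TCDD on 4 of 4 days and genes such as CD69 and CD96 lower, but 0 of 17344 genes passed in either direction (edgeR, smallest adjusted p = 0.0795). At unadjusted p below 0.05 there were 2294. DESeq2 called 395 up and 368 down, limma-voom called 0 (2451 unadjusted), and the edgeR test called 15 up and 29 down with cells thinned to 1500 counts and 10 up and 11 down with no low-count filter. Unadjusted counts were 1289 without day 14 and 721 without the day block. Higher on 4 of 4 days were MMP2, a gelatinase (+1.51, SE 0.120, adjusted p = 0.0795), and ACP5, an acid phosphatase of macrophages and osteoclasts (+1.24). So were CSTA (+0.80), UPP1 (+0.92), CLMN (+0.94), NINJ1 (+0.70), ASGR1 (+0.65), CD151 (+0.56), the myeloid transcription factor CEBPB (+0.55) and LGALS1 (+0.54). Lower on 4 of 4 days were CD69, an early activation marker of lymphocytes (−1.47, SE 0.130, adjusted p = 0.0795), CD96 (−1.25), C12orf75 (−1.18), TSPAN13 (−0.99) and GNG2 (−0.97). COBLL1, SUSD3, STRBP, GNAI1, JUP, TRANK1 and AFF1 followed, from −0.88 to −0.44, with adjusted p values of 0.128 to 0.141.

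Oxidative stress, alarmin and lysosome genes were among the other sets called higher with TCDD. NRF2 targets, which respond to oxidative stress, had a median of +0.50 over 11 genes (camera adjusted p = 7.82e-11; estimated correlation, adjusted p = 0.176). HMOX1 (+0.52), FTL (+0.65, uncertain because of its pseudogenes) and SRXN1 (+1.25) were higher on 4 of 4 days, with 0 passing over all genes and 8 adjusted over the list alone. Alarmins (S100A9 +1.04, S100A8 +0.85, S100A11 +0.50, S100A6 +0.47; adjusted p = 2.1e-07) had 4 of 6 adjusted over the list alone, but a median of −0.08 on day 28, where S100A9 (−0.28) and S100A8 (−0.20) were lower. Lysosome genes (CTSL +0.60; adjusted p = 1.24e-08) and glycolysis genes (HK2 +0.47, PKM +0.34, ENO1 +0.32, PGAM1 +0.27; adjusted p = 1.04e-05) had 5 of 15 and 5 of 14. With an estimated correlation these 3 calls had adjusted p = 0.176. Within the cell classes tested below, lysosome genes were not called (camera adjusted p = 0.182 to 0.789). Their medians there were +0.07 in HSPC-like, −0.06 in dendritic-like, −0.02 in granulocyte-monocyte progenitor-like and −0.08 in monocyte-like cells. Monocyte markers (CSTA, CD14 +0.57, VCAN +0.59; adjusted p = 3.2e-07; estimated, adjusted p = 0.249) had 6 of 12 adjusted over the list alone, with a positive median on days 7, 14 and 21 and −0.29 on day 28 (8 of 12 lower). Cytokines and chemokines (CXCL8 +1.02, IL10 +0.82, CCL22 +1.22, IL1RN +0.50; adjusted p = 0.00623; estimated, adjusted p = 0.192) had 1 of 16. No member of these lists passed over all genes. Monocyte-like cells were also the larger share with TCDD on all 4 days (34.0% against 19.1% on day 7).

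Cell cycle and stress lists gave weaker results, none with a member past the threshold over all genes. S phase genes (CLSPN +0.27, RRM2 +0.30, FEN1 +0.18, UHRF1 −0.40) were called higher (camera adjusted p = 0.00552; estimated, adjusted p = 0.551), but not without day 14 (adjusted p = 0.125). G2/M genes (PLK1 +0.26, AURKA +0.16) were not called (adjusted p = 0.0989), except without day 28 (adjusted p = 0.00928, with an estimated correlation adjusted p = 0.495). Immediate early and stress genes (JUN +0.77, and HSPA1A +0.23, which shares reads with HSPA1B; adjusted p = 0.0297; estimated, adjusted p = 0.494) lost the call without day 14 (adjusted p = 0.152) or day 21 (adjusted p = 0.319). Adjusted over the list alone these 3 lists had 0 members. Of p53 targets (adjusted p = 0.0874, but 0.00469 without day 14, and then adjusted p = 0.333 with an estimated correlation), FAS, TNFRSF10B and RRM2B passed adjusted over the list alone. Hypoxia genes were not called (adjusted p = 0.246; 1 member adjusted over the list alone, NDRG1 +0.40). For cholesterol synthesis the median was 0.01 and the mean −0.007, opposite in sign (camera adjusted p = 0.986, but lower at 0.0455 without day 21, and then adjusted p = 0.616 with an estimated correlation). Its single days went both ways: −0.323 on day 7 (16 of 18 lower), +0.095 on day 14, +0.345 on day 21 (18 of 18 higher) and −0.309 on day 28.

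Antigen presentation and interferon genes were lower with TCDD from day 14 on. The 18 type I interferon genes, antiviral effectors such as MX1 (−0.99), IFI44L (−1.58), ISG15 (−0.42) and XAF1 (−0.40), had medians of −0.12, −0.54, −0.51 and −0.74 over the days. Camera called them lower (adjusted p = 1.94e-08; estimated, adjusted p = 0.176), with 0 passing over all genes and 5 adjusted over the list alone. MHC class II genes, which present antigen, had +0.07 on day 7 and −1.25, −0.30 and −0.996 later, with 10 of 10 lower on each of those 3 days. HLA-DQA1 (−0.91), HLA-DPB1 (−0.83), HLA-DPA1 (−0.81) and HLA-DRB1 (−0.47) share reads with related genes and are uncertain in level. The list was called lower (adjusted p = 9.06e-08; estimated, adjusted p = 0.35), with 0 members by either adjustment. The TCDD libraries of days 14, 21 and 28 also held fewer plasmacytoid dendritic-like cells, which express both sets (0.253% against 7.59% on day 14).

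B lineage, T lineage, plasmacytoid dendritic and dendritic markers were called lower with TCDD. The 14 B lineage markers were lower on 14 of 14 genes on days 14, 21 and 28, with medians of −1.77, −1.71 and −3.58 and −0.04 on day 7. VPREB1, part of the surrogate light chain of B cell precursors, was at 210 CPM with vehicle and 12.3 CPM with TCDD on day 28. Examples from the model were VPREB3 (−4.37), RAG2 (−4.06), VPREB1 (−2.74) and CD79A (−2.46), none passing over all genes and 12 adjusted over the list alone (camera adjusted p = 2.22e-17; estimated, adjusted p = 0.208). Plasmacytoid dendritic markers (CLEC4C −3.999, PTCRA −3.71, MZB1 −2.13, TCF4 −1.04; adjusted p = 5.55e-16; estimated, adjusted p = 0.208) had 9 of 12 adjusted over the list alone. T lineage markers (TRAC −2.19, CD3E −2.11; adjusted p = 9.39e-11; estimated, adjusted p = 0.192) had 4 of 7. These genes lay near the floor (mean CPM 1.57 for TRAC and 2.22 for CD3E), and no cluster was named T lineage-like. Dendritic markers (CD1C −2.88, CD1E −2.19, CLEC10A −1.05; adjusted p = 1.59e-11; estimated, adjusted p = 0.176) had 5 of 11. NK markers were mixed (GNLY −2.44, NKG7 +0.34; adjusted p = 0.0105; estimated, adjusted p = 0.427), with 0 members by either adjustment, and were not called without day 28 (adjusted p = 0.568). B lineage-like cells were at 0.130% with TCDD and 14.3% with vehicle on day 28.

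Erythroid, megakaryocyte and mast cell markers were lower with TCDD on days 7 and 14 and not on day 21, and mast cell markers again on day 28 (median −0.46, 8 of 11 lower). Erythroid medians were −2.86, −2.50, +0.52 and 0 (HEMGN −1.03, SLC4A1 −3.44, CA1 −4.30; camera adjusted p = 0.000773; estimated, adjusted p = 0.494). On day 7 HBB was at 1506 CPM with vehicle and at 0.0155 CPM (2 counts, interval 0.00188 to 0.0560) with TCDD, and AHSP at 104 CPM and at 0.00776 CPM (1 count, interval 0.000196 to 0.0432). Erythroid-like cells were at 12.7% and 0.939% that day. Megakaryocyte markers (PF4 −2.77, GP9 −2.04; adjusted p = 0.000138; estimated, adjusted p = 0.427) and mast cell markers (HPGDS −1.22, KIT −0.58; adjusted p = 0.00383; estimated, adjusted p = 0.494) followed, the mast call being lost without day 7 (adjusted p = 0.232) or day 14 (adjusted p = 0.0704). Neutrophil markers (LTF −2.04, CRISP3 −2.19, FCGR3B −2.08; adjusted p = 4.85e-06; estimated, adjusted p = 0.316) had a positive median only on day 21 (+0.12). HSPC markers were lower (CD34 −0.996, SPINK2 −0.58, SMIM24 −0.42; adjusted p = 0.00623; estimated, adjusted p = 0.427; without day 28, adjusted p = 0.165). Stem cell transcription factors (HOXB4 −0.38, MLLT3 −0.40, MEIS1 −0.27; adjusted p = 0.0134; estimated, adjusted p = 0.402) lost the call without day 7 (adjusted p = 0.175) or day 28 (adjusted p = 0.0819). No member of these lists passed over all genes. Adjusted over the list alone HSPC markers had 4, mast cell markers 1, and the other 4 of these lists 0. Macrophage (adjusted p = 0.986; MARCO +1.11, MRC1 −1.32), stromal (0.399) and eosinophil markers (0.62; median −0.05 and mean −0.07 against a camera direction of up) were not called. Nor were granulocyte-monocyte progenitor markers (0.62; IGLL1 −1.50, MPO +0.37), except higher without day 7 (adjusted p = 0.00111, estimated, adjusted p = 0.557). Of these 4 lists, eosinophil markers had 1 member adjusted over the list alone (RNASE2 +0.51) and the others 0, with 0 over all genes.

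**Figure D2:**
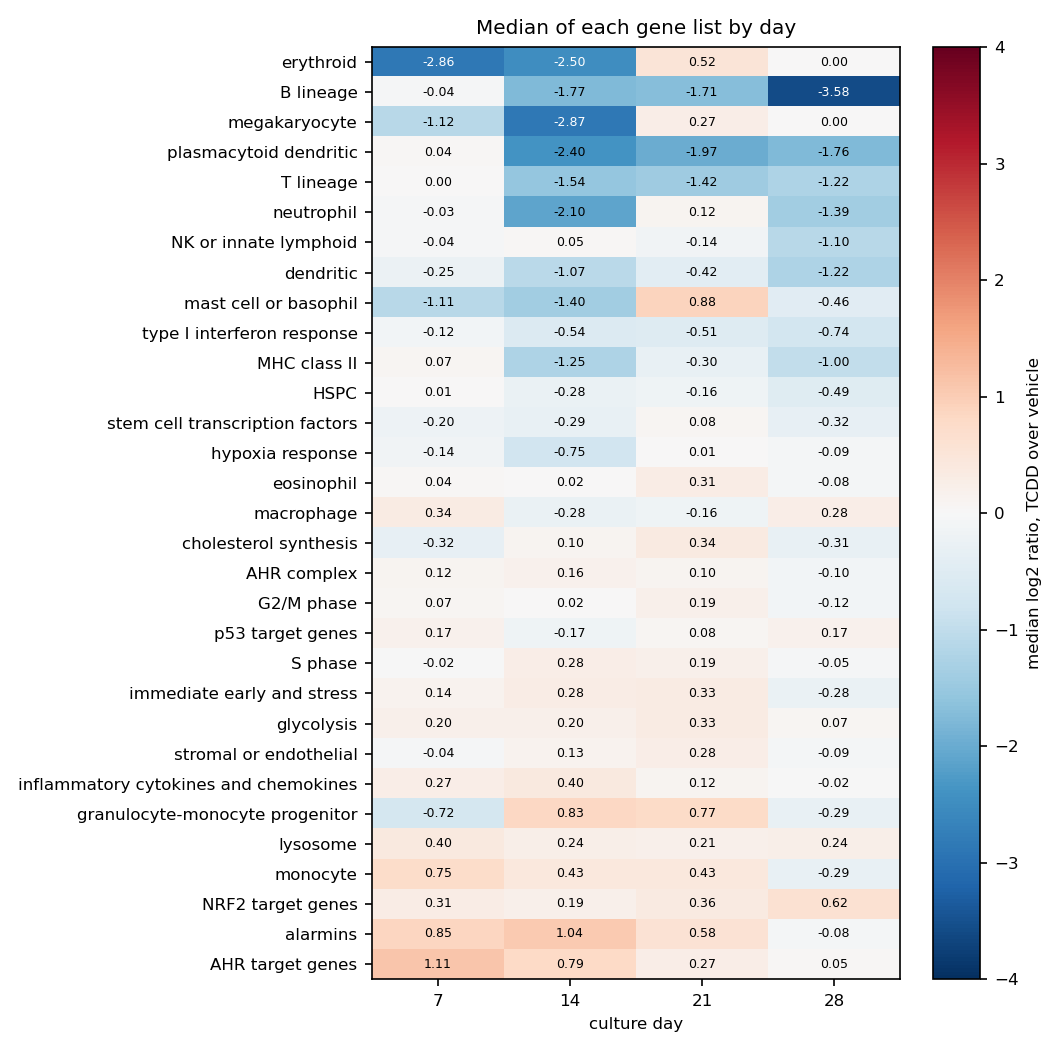
Median log2 ratio of TCDD over vehicle (colour and number) for each of the 31 gene lists (y axis) on each culture day (x axis), from 1 vehicle and 1 TCDD library per day, without a test. AHR targets had their highest median on day 7 (1.11), and B lineage markers their lowest on day 28 (−3.58).

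On which days did single genes differ most? Genes with 100 CPM or more in the higher library were ranked by ratio, without a test. The median ratio of all genes was 0.03, −0.04, 0.01 and −0.08 on the 4 days, and TMM scaling moved CYP1B1 on day 28 from 1.09 to 1.26. On day 7 the highest were TMEM176B (+1.97), CYP1B1 (+1.94), the lysosomal fucosidase FUCA1 (+1.91), S100A9 (+1.56) and F13A1 (+1.48), genes of monocytes among them. The lowest were the erythroid genes HBB, AHSP and HBD (−10.54, −6.70 and −5.73), then APOC1 (−5.08) and HPGD (−1.73). On day 14 NME2 (+2.87), CYP1B1 (+2.49), FUCA1 (+2.08), S100A9 (+1.78) and S100A8 (+1.65) were highest. The platelet chemokines PPBP (−7.27) and PF4 (−4.89) were lowest, with JCHAIN (−4.22), HBA2 (−3.93) and LTB (−3.92). On day 21 the metallothionein MT2A (+2.31), CYP1B1 (+1.58), NME2 (+1.57), the chemokine CXCL8 (+1.37) and RNASEK (+1.33) were highest, and VPREB1 (−2.71), HBB (−2.13), LTB (−2.01) and IGLL1 (−1.20) lowest. In the vehicle day 21 library 1 monocyte-like cell held 1954 of the 7668 HBB counts. On day 28 the metal-binding MT1H (+6.91), MT1G (+6.69), MT2A (+3.78) and MT1X (+3.28) and NME2 (+2.06) were highest, and VPREB1 (−3.99), IGLL1 (−3.74), IGHM (−2.85), CD24 (−2.74) and MRC1 (−2.30) lowest. NME2 and RNASEK overlap read-through genes, and metallothioneins are close paralogs, so their levels are uncertain.

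**Figure D3:**
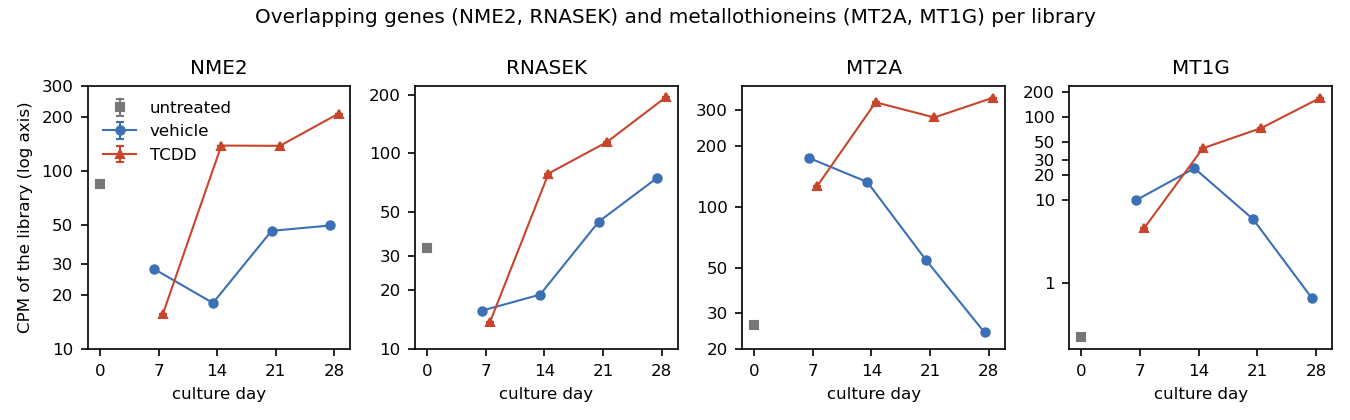
CPM (log axis) of NME2, RNASEK, MT2A and MT1G by culture day in the 9 libraries, 1 point per library. The TCDD points lay below vehicle on day 7 and above on days 14, 21 and 28 in all 4 panels.

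Across 8299 genes of at least 10 CPM, the TCDD over vehicle ratios of days 14, 21 and 28 resembled each other more than those of day 7. Between days 14 and 21 Pearson's r was 0.467 (Spearman's rho 0.563), between 14 and 28 0.369 (0.283) and between 21 and 28 0.369 (0.252). Day 7 had r = 0.316 (rho 0.118) with day 14, −0.014 (0.137) with day 21 and 0.001 (−0.065) with day 28. These last 2 values of r changed sign, to 0.014 and −0.033 over genes of at least 50 CPM and to 0.047 and −0.021 with 5 CPM added. These are correlations across genes of 6 pairs of days, and genes are not independent replicates.

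Did the TCDD effect change with day? RHAG, the Rhesus-associated glycoprotein of red cell precursors, was the 1 of 17344 genes that passed: its effect rose by 5.07 log2 per 7 days (SE 0.139, adjusted p = 0.00485). RHAG was at 31.8 CPM with vehicle and 0.18 CPM with TCDD on day 7, 49.96 and 9.38 on day 14, 1.61 and 10.2 on day 21, and 0 and 0.02 on day 28, against 2.52 at day 0. Erythroid-like cells were at 12.7% and 0.939%, 10.8% and 3.99%, and 0.0297% and 1.59% on days 7, 14 and 21, with 0 cells in both day 28 libraries. Next by p were FAM178B (+6.56, adjusted p = 0.0579), MT1X (+1.25, adjusted p = 0.0579), MT2A (+1.44, adjusted p = 0.0700) and PAPPA (+4.11, adjusted p = 0.0700), which did not pass. In the edgeR test 0 genes passed with a falling effect. At unadjusted p below 0.05 there were 1470 genes. DESeq2 called 116 up and 102 down, and limma-voom 0 (1611 unadjusted). Without day 21 the edgeR test called 0, without day 14 it called 7 and without day 28 it called 3.

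Which cells each culture held was compared by cluster-based classes. Monocyte-like cells were the larger share with TCDD on 4 of 4 days: 19.1% with vehicle and 34.0% with TCDD on day 7, 16.4% and 33.5% on day 14, 8.14% and 25.1% on day 21, and 9.76% and 14.9% on day 28. Macrophage-like cells were at 15.3% and 29.4% on day 28. Most were in cluster 3 (731 and 570 cells), while 31 and 90 were in cluster 31, which is led by metallothioneins that differed between arms. Plasmacytoid dendritic-like cells, the main producers of type I interferon, were at 7.59% and 0.253% on day 14, 10.6% and 1.18% on day 21, and 2.70% and 0.260% on day 28, with 0.123% and 0.167% on day 7. B lineage-like cells made up 14.3% of the vehicle library on day 28 (795 cells) against 0.130% with TCDD (3 cells; ratio 0.00906, interval 0.00187 to 0.0266). On day 21 they were 51 cells with vehicle and 0 of 1947 with TCDD, which allows up to 0.154%.

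Erythroid-like cells were at 12.7% with vehicle and 0.939% with TCDD on day 7, 10.8% and 3.99% on day 14, and 0.0297% (1 cell) and 1.59% on day 21. The hemoglobin-led cluster 28 held 192 cells of vehicle day 7 and 0 of TCDD day 7. Neutrophil-like cells were fewer with TCDD on days 14, 21 and 28 (8.23% and 2.38%, 16.6% and 14.7%, 21.6% and 18.5%), with overlapping intervals on day 21. Dendritic-like cells were at 9.07% and 4.10% on day 14, 9.56% and 9.71% on day 21, and 3.21% and 0.952% on day 28. Mast cell or basophil-like cells were at 0.517% and 0.0417% on day 7, 2.39% and 0.455% on day 14, and 0.0594% and 0.514% on day 21, and megakaryocyte-like cells at 0.640% and 0.0417%, 1.93% and 0.202%, and 0.742% and 1.08%. HSPC-like cells were at 6.59% and 14.8% on day 7, where cluster 20 held 102 cells with vehicle and 422 with TCDD, and within counting error of each other later. Granulocyte-monocyte progenitor-like cells were at 19.1% and 8.85% on day 7 but 11.2% and 20.1% on day 14. No class or cluster passed the test over days (edgeR; 0 of 23, and 4 at unadjusted p below 0.05, with plasmacytoid dendritic −2.93, B lineage −4.65 and cluster 7 +2.46 log2, all adjusted p = 0.118). Cluster 7 is led by metallothioneins that differed between arms, so its size is not a result, though it passed without day 7. Without that day plasmacytoid dendritic-like cells also passed (−3.75, adjusted p = 0.0386). Without day 21 they passed too (−2.83), as did B lineage (−4.42), megakaryocyte (−3.46), mast cell (−2.80) and erythroid-like cells (−2.56). The smallest p of the exact sign-flip test over 4 days is 0.125.

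Scoring thresholds set after seeing the data left 11 of 40 clusters unnamed. Cluster 8, close to both B lineage and HSPC (JCHAIN, CD79A, CD96, LTB), was at 0.787% with vehicle and 0.689% with TCDD on day 7, 7.33% and 0.859% on day 14, 12.1% and 3.54% on day 21, and 5.15% and 2.34% on day 28. Cluster 30, nearest to T lineage, was at 0.344% and 0.417%, 3.11% and 0.556%, 1.60% and 1.34%, and 0.198% and 0.303% on these days. Cluster 14, nearest to monocytes, was at 0 and 0, 0.418% and 0.303%, 5.08% and 5.65%, and 6.36% and 12.5%. Cluster 18, also near monocytes, was at 0 and 0.0417%, 0.232% and 0.152%, 4.60% and 4.47%, and 7.11% and 7.48%. Cluster 27, a dividing HSPC-related cluster, was at 3.96% and 4.09%, 0.858% and 1.77%, 0.297% and 0.411%, and 0.0720% and 0.0865%. Cluster 23, scored nearest to T lineage but led by genes such as KLRB1, CD96 and JCHAIN, was at 0.271% and 0.459%, 2.88% and 0.556%, 6.32% and 1.69%, and 3.24% and 1.51%. Of the clusters with fewer than 3 markers, cluster 5 was at 12.7% and 12.5%, 2.53% and 5.61%, 1.16% and 1.39%, and 0.108% and 0.519%, and cluster 12 at 7.33% and 5.55%, 5.20% and 8.85%, 1.07% and 1.69%, and 0.396% and 0.346%. Cluster 7, whose size is not a result, was at 9.97% and 13%, 1.37% and 8.24%, 0.178% and 2.67%, and 0.0180% and 0.260%. Cluster 36, of low counts, was at 0.172% and 0.0417%, 1.51% and 0.455%, 0.891% and 1.18%, and 0.180% and 0.0433%. Cluster 39 was at 0 and 0, 0.0232% and 0, 0.327% and 0.0514%, and 0.0900% and 0.130%.

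**Figure D4:**
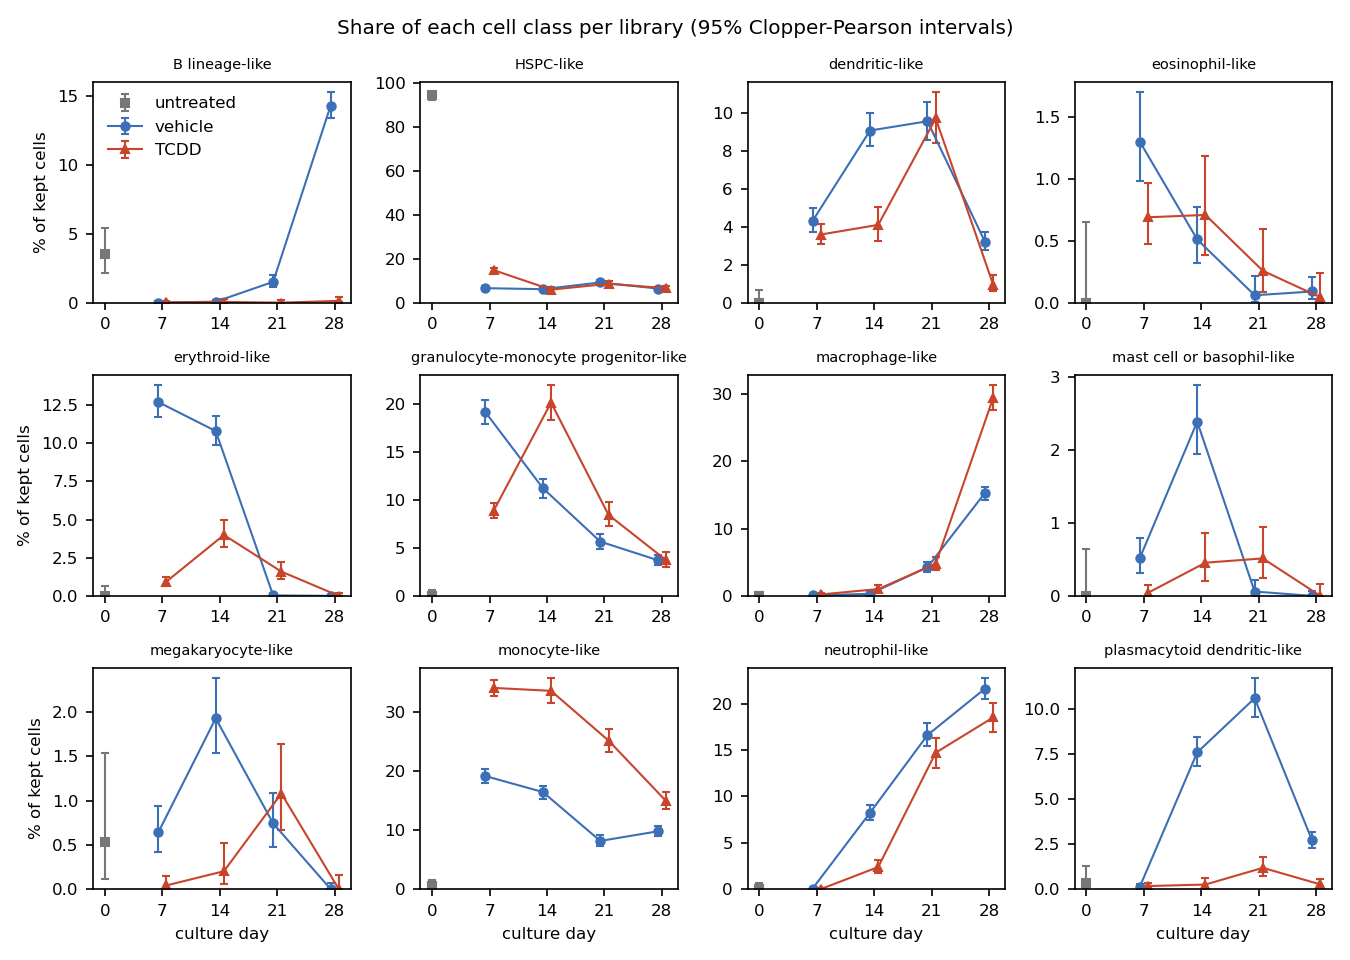
Share of kept cells (y axis, percent) in each of 12 named classes by culture day (x axis) in the 9 libraries, with 95% Clopper-Pearson intervals that cover counting error only. Monocyte-like shares were higher with TCDD on 4 of 4 days (34.0% against 19.1% on day 7), and plasmacytoid dendritic-like shares lower on days 14, 21 and 28 (0.253% against 7.59% on day 14).

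Changes within a class were tested in the 4 classes with enough cells. In HSPC-like cells CRHBP, a marker of primitive HSPCs, rose with TCDD (+1.48, SE 0.138, adjusted p = 0.0021; 46.1 and 134 CPM on day 7, 15.8 and 50.1 on day 14). It leads cluster 20, which held 422 of 708 cells of the class with TCDD and 102 of 268 with vehicle on day 7, and 17 of 152 and 64 of 356 on day 28. Within cluster 20 alone CRHBP was at 162 and 281 CPM on day 7, 88.0 and 182 on day 14, 16.7 and 119 on day 21, and 12.2 and 31.3 on day 28, where the intervals overlapped. In cluster 1 it was higher on days 7 (7.82 and 17.9) and 28 (3.86 and 6.13) and not on days 14 and 21. HGF, hepatocyte growth factor, fell (−1.28, SE 0.169, adjusted p = 0.0265), and in cluster 1 alone it was lower on 4 of 4 days (52.6 and 15.9 CPM on day 14), with overlapping intervals on day 7. The third of these was VPREB1, which fell (−1.63, adjusted p = 0.0047), was lower on 4 of 4 days in cluster 1 (38.0 and 7.25 CPM on day 14), and is named after its values were seen. AHR targets had a median of +0.35 (camera adjusted p = 0.00152, with an estimated correlation 0.356, fry adjusted p = 0.0212). Of their members 0 passed over all genes and 1 adjusted over the list alone. G2/M genes were at −0.30 (camera adjusted p = 1.45e-06, estimated 0.526, fry 0.716). S phase genes were at −0.19 (camera adjusted p = 6.07e-07, estimated 0.563, fry 0.736). Markers of other types were also lower in the class: B lineage −0.44 (6 genes; camera adjusted p = 1.64e-07; estimated, adjusted p = 0.356; 1 adjusted over the list alone) and plasmacytoid dendritic −0.36 (6 genes; 0.000414; estimated, adjusted p = 0.456; 2). Of 12194 genes 1 rose and 2 fell (589 at unadjusted p below 0.05; DESeq2 called 2 up and 3 down). Without day 7 the counts were 39 and 32, without day 21 0 and 0, and without day 28 none fell.

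In granulocyte-monocyte progenitor-like cells CYTL1, a cytokine-like protein of CD34+ cells, rose (+1.04, SE 0.132, adjusted p = 0.0128). In cluster 9 alone it was at 97.2 CPM with vehicle and 293 with TCDD on day 7, 52.1 and 118 on day 14, 54.4 and 103 on day 21, and 37.5 and 72.7 on day 28, and it was also higher on 4 of 4 days in cluster 13, with overlapping intervals on day 28. TRAPPC5 rose (+1.47, adjusted p = 0.0472) but overlaps another gene. Outside the rule, and named after their values were seen, AHRR (+1.99, adjusted p = 0.0128) and MMP2 (+1.21, adjusted p = 0.0441) rose. AHRR was at 4.74 CPM with vehicle and 20.8 with TCDD on day 7 and at 1.32 and 4.62 on day 14, against 2.34 and 3.22, and 1.42 and 4.94, in the erythroid-like cluster 17. On day 14 background and expression of AHRR therefore cannot be told apart in this class. It was at 0.36 and 4.58 CPM on day 21 and at 2.25 and 5.65 on day 28. The globins HBB (−5.81) and HBA1 (−5.12, uncertain because of HBA2), named in the same way, passed as lower, both at adjusted p = 0.0128. HBB in this class was at 20.2 CPM with vehicle and 0.102 CPM (1 count) with TCDD on day 7. In the vehicle day 7 library HBB also stood at 22.3 CPM in monocyte-like and 10.4 CPM in HSPC-like cells, against 10170 in erythroid-like cells, which were fewer with TCDD on days 7 and 14. The globin counts of granulocyte-monocyte progenitor-like cells are therefore read as background and not as a change in this class. AHRR overlaps PDCD6, and without overlapping genes 2 were called up and 2 down. The AHR target list had a median of −0.004 against a camera direction of up (adjusted p = 0.000277; estimated, adjusted p = 0.354). G2/M genes had a median of +0.49 (camera adjusted p = 4.08e-13), S phase genes +0.26 (9.46e-10) and neutrophil markers −0.80 (0.000233), each with an estimated adjusted p = 0.42 and with 0, 0 and 2 members adjusted over the list alone. In all, of 11643 genes 4 rose and the 2 lower were these globins (559 at unadjusted p below 0.05; DESeq2 called 8 and 1). Without day 7 the counts were 57 and 28, without day 14 or day 28 0 and 0, and with classes by highest marker score 160 and 194.

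In monocyte-like cells antigen presentation genes were lower and AHR targets higher with TCDD, though 0 of 12991 genes passed (edgeR; 1123 at unadjusted p below 0.05; DESeq2 37 up, 78 down). All 10 MHC class II genes passed adjusted over the list alone (median −1.03; camera adjusted p = 1.05e-36; estimated, adjusted p = 0.131). Different clusters held the class: clusters 2 and 6 on day 7, cluster 11 on day 14 and cluster 4 later, while TCDD day 21 still held 68, 45 and 97 cells of clusters 2, 6 and 11 among its 489, against 0, 3 and 0 of 274 with vehicle. HLA-DPB1 (−1.37) and CYP1B1 (+0.98) kept their direction on 4 of 4 days without passing (adjusted p = 0.0818). In cluster 4 alone HLA-DPB1 was at 1053 CPM with vehicle and 346 with TCDD on day 21, and at 993 and 270 on day 28. CYP1B1 there was at 232 and 505 CPM on day 21 and at 93.0 and 171 on day 28. Of 17 interferon genes 9 passed adjusted over the list alone (median −0.72; adjusted p = 4.27e-16; estimated, adjusted p = 0.131), and 5 of 8 AHR targets (median +0.47; adjusted p = 3.97e-06; estimated, adjusted p = 0.131). G2/M genes had a median of +0.92 (18 of 18 adjusted over the list alone; adjusted p = 3.16e-21; estimated, adjusted p = 0.168) and S phase genes +0.68 (16 of 18; adjusted p = 1.73e-25; estimated, adjusted p = 0.131), and cluster 6, led by dividing-cell genes, held 248 of 663 such cells with TCDD and 115 of 707 with vehicle on day 14. Markers of other types were also lower in the class: dendritic −2.45 (6 of 6 adjusted over the list alone; adjusted p = 9.27e-29; estimated, adjusted p = 0.131), B lineage −1.71 and erythroid −5.09 (camera adjusted p = 2.5e-12 and 1.18e-14; estimated, adjusted p = 0.131 for both). In the vehicle day 21 library 1 of these cells held 1954 of the class's 1956 HBB counts. The class's own monocyte markers were lower as well (median −0.31; camera adjusted p = 5.54e-05; estimated, adjusted p = 0.177). Granulocyte-monocyte progenitor markers were higher (median +0.55; camera adjusted p = 0.00251; estimated, adjusted p = 0.323). Without day 7 the test called 2 up and 5 down, without day 14 2 down and without day 21 1 down.

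Dendritic-like cells had 3 testable days and 0 of 12027 genes past the threshold (edgeR; 1138 at unadjusted p below 0.05; DESeq2 21 up, 28 down; 13 and 5 without day 7, 4 and 17 without day 14). MHC class II genes had a negative median, as in monocyte-like cells (−0.45, with 8 of 10 adjusted over the list alone, camera adjusted p = 3.75e-10, with an estimated correlation 0.323). The list was not called in HSPC-like (median −0.028, camera adjusted p = 0.643) or granulocyte-monocyte progenitor-like cells (+0.205, camera adjusted p = 0.116). Interferon genes were at −0.88 with 8 of 17 adjusted over the list alone (adjusted p = 8.71e-10; estimated, adjusted p = 0.323). AHR targets were at +0.64 with 4 of 6 (adjusted p = 1.28e-06; estimated, adjusted p = 0.323), among them NQO1 (+1.27) and TIPARP (+0.77), neither passing over all genes (adjusted p = 0.169 and 0.186). The class's own dendritic markers were lower as well (median −1.17; 6 of 10 lower and 2 higher adjusted over the list alone; adjusted p = 3.31e-05; estimated, adjusted p = 0.323). So were markers of other types: erythroid −4.49, B lineage −0.95, granulocyte-monocyte progenitor −0.95 and monocyte −0.36 (camera adjusted p = 1.22e-06, 9.55e-05, 2.41e-06 and 2.41e-06; estimated, adjusted p = 0.323 for each). The erythroid list held 4 genes. HBB in these cells was at 103 CPM with vehicle and 0 with TCDD on day 7, and at 84.25 and 0 on day 21. The day 7 value with vehicle was above the 22.3 CPM of monocyte-like, 20.2 of granulocyte-monocyte progenitor-like and 10.4 of HSPC-like cells. Background alone may therefore not account for it, and the source of these day 7 counts was not tested. Vehicle day 21 held 1 erythroid-like cell, and the source of its HBB counts was not tested.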

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

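All tests of the early cells described in this part were chosen after the result was seen, and the tests on CYP1B1 were divided by cluster after their values were seen.

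RHAG, the Rhesus-associated glycoprotein of red cell precursors, drew attention because its TCDD effect differed between days: the effect rose by 5.07 log2 per 7 days in the edgeR interaction test. Shares of 3 cell classes lay on opposite sides of vehicle on different days, and these differences between days were not tested. Erythroid-like cells had a TCDD over vehicle ratio of 0.0739 on day 7, 0.370 on day 14 and 53.6 on day 21 (interval 8.94 to 2190, from 1 vehicle cell), where 29 of the 31 TCDD cells were in cluster 17. Granulocyte-monocyte progenitor-like cells had ratios of 0.463, 1.80 and 1.49 on these days, and mast cell or basophil-like cells 0.0808, 0.190 and 8.65.

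In the TCDD day 21 library 239 of 1947 cells (12.3%) were in clusters 2, 6, 11 and 17, and 52 in cluster 7, whose size is not a result; these clusters were chosen after seeing the data for at least 20 cells there and under 10 in each other library of days 21 and 28, so the contrast with those libraries is set by the choice. The barcodes argue against a mixture of sequence data with an earlier library, since at most 0.344% of them (1 of 291) occurred in any earlier library. The highest share in any other library was 0.687% (2 of 291), with vehicle day 28. Vehicle cells of day 14 are argued against in clusters 6, 7 and 11, where CYP1B1 CPM was at least 2.34 times that of vehicle day 14, and stay open in cluster 2 (ratio 1.06) and in cluster 17 (0.318, from 1 count). TCDD cells of day 14 are argued against in clusters 2, 6 and 7, where CYP1B1 was at most 0.654 times that of TCDD day 14, and stay open in cluster 11 (0.983) and in cluster 17 (0.027, from the same count). A mixture of both arms or of day 7 cells was not weighed, and a slower course of maturation with TCDD may also hold such cells, which stays open and untested.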

How the results depend on the processing

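The alternatives with a separate term for the TCDD libraries of days 14 to 28 (the late term), without read-through or overlapping genes, and without the early clusters of TCDD day 21 were chosen after seeing the data. The late term leaves the treatment effect to the day 7 pair, 1 library per arm assumed to vary like the others, so its values describe day 7 and do not test the effect over days. Over 947 recomputed values, 132 of the summary values stayed the same, 80 moved and 4 reversed. Of the values of single genes and classes, 650 stayed the same, 50 newly passed, 3 moved and 28 reversed. The new passes came from DESeq2 (25), no low-count filter (11), cells thinned to 1500 counts (8), and leaving out day 21 (5) or day 7 (1), in the same direction. The cause was not tested for any change given here. All deposited barcodes entered the class shares only as the denominator, eosinophil-like shares have no value at Leiden resolutions 0.6 and 2, and the dendritic class, with 3 testable days, has no separate fit without day 28.

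Treatment effect: the edgeR test called 0 genes, against 10 higher and 11 lower with no low-count filter, 395 and 368 with DESeq2, and 15 and 29 with cells thinned to 1500 counts. For day 7 alone, by the late term, it called 1 lower, HBB, named after its values were seen. Read-through or overlapping genes left out gave 0 and 0. Trend over days: leaving out 1 day gave 988 to 2482 rising and 1145 to 2765 falling genes, the lowest without day 28 and then 1557 and 1660 without day 7. The vehicle libraries alone gave 798 and 846, and with day 0 added 3 and 0. Change of the treatment effect with day: no low-count filter gave 7 rising and 1 falling, DESeq2 116 and 102, limma-voom 0 rising, and the stricter cell filter 11 and 2. Leaving out 1 day gave 0 to 7 rising, with 7 without day 14, 0 without day 21 and 3 without day 28. Gene lists: camera with an estimated correlation called 0 higher and 0 lower, and fry 0 and 0. For day 7 alone, by the late term, camera called 5 and 8.

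Class shares: leaving out day 7 gave 1 class or cluster higher and 1 lower, and leaving out day 21 gave 5 lower, so that leaving out 1 day gave 0 to 1 higher and 0 to 5 lower. The HSPC-like share turned to −0.071 log2 by highest marker score and ranged from −0.038 to 0.381 when 1 day was left out. The eosinophil-like share turned to −0.78 with the stricter cell filter and −0.074 with TMM on class counts, and ranged from −0.39 to 0.58 (−0.073 without day 14, −0.388 without day 21). The granulocyte-monocyte progenitor-like share turned to −0.006 with TMM on class counts and ranged from −0.17 to 0.48 (−0.174 without day 14, −0.085 without day 21). The erythroid-like share ranged from −2.56 to 1.12, with 1.123 without day 7 and 0.162 without day 14.

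Within classes, no low-count filter gave 39 higher and 50 lower in HSPC-like, 131 and 215 in dendritic-like, 50 and 45 in granulocyte-monocyte progenitor-like and 159 and 141 in monocyte-like cells. DESeq2 gave 2 higher in HSPC-like cells, 21 and 28 in dendritic-like, 8 and 1 in granulocyte-monocyte progenitor-like and 37 and 78 in monocyte-like cells. Leaving out 1 day gave 0 to 39 higher and 0 to 32 lower in HSPC-like, 0 to 13 and 0 to 17 in dendritic-like (13 and 5 without day 7, 4 and 17 without day 14), 0 to 57 and 0 to 28 in granulocyte-monocyte progenitor-like, and 0 to 2 and 0 to 5 in monocyte-like cells (2 and 5 without day 7, 2 lower without day 14, 1 lower without day 21). Classes by highest marker score gave 0 lower in HSPC-like, 1 and 3 in dendritic-like and 160 and 194 in granulocyte-monocyte progenitor-like cells, and leaving out overlapping genes gave 2 higher in the last.

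Single genes that did not pass reversed as follows in the treatment effect. For day 7 alone, by the late term, SLC7A5 was at 0.21, EREG −0.92, PTGES3 −0.014, HSP90AB1 −0.112, AHR 0.152 and NCOA1 0.107. When 1 day was left out EREG ranged from −0.402 (day 21) to 0.699 (day 7), STC2 from −0.884 (day 28) to 1.432 (day 21), with −0.393 without day 7, and AHR from −0.262 (day 14) to 0.176 (day 28). NCOA1 ranged from −0.062 (day 21) to 0.043 (day 28), with 0.029 without day 14. STC2 was at −0.093 with the stricter cell filter, −0.103 with doublets removed and −0.021 without the day block. NCOA1 was at 0.013 with no low-count filter and 0.040 with the stricter cell filter. The single-day log2 ratio of CYP1B1 moved beyond its counting interval to 1.913 (5 CPM added) and 1.883 (TMM) on day 7, 2.374 (5 CPM) on day 14, 1.510 (5 CPM) on day 21, and 1.054 (all barcodes) and 1.256 (TMM) on day 28. Pearson's r between days 7 and 21 was 0.014 over genes of at least 50 CPM and 0.047 with 5 CPM added, and between days 7 and 28 it was −0.033 and −0.021. Depth limits the day 0 values most, at 567 kept cells, and CYP1A1, at 0 to 68 counts per library.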

Other observations

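The tests of explanations and the splits in this part were chosen after the result was seen. The test used within classes was fixed before the data were examined, but the thresholds that named the classes were not. MMP2 in granulocyte-monocyte progenitor-like cells was named after its values were seen.

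AHR and its target CYP1B1 were unevenly spread over the classes. In the vehicle day 7 library AHR was at 88.7 CPM in monocyte-like and 98.0 CPM in dendritic-like cells, against 6.56 in HSPC-like and 6.04 in granulocyte-monocyte progenitor-like cells. CYP1B1 that day was at 790 CPM with vehicle and 1316 with TCDD in monocyte-like cells, and 335 and 753 in dendritic-like cells. In HSPC-like (5.47 and 8.78) and granulocyte-monocyte progenitor-like cells (3.0 and 10.3) it was below the 16.4 and 14.5 CPM of the erythroid-like cluster 17. Cluster 17 did not follow the rise of the whole libraries from 132 to 510 CPM, so background and expression cannot be told apart in these 2 classes. In granulocyte-monocyte progenitor-like cells CYP1B1 was higher with TCDD on each day, at 0.26 to 2.12 CPM after day 7, without passing (+1.755, edgeR adjusted p = 0.195). NQO1 was at 20.3 and 43.0 CPM in monocyte-like cells. MMP2, a gelatinase, had log2 effects of +1.33 (edgeR adjusted p = 0.0805) in HSPC-like, +1.21 (adjusted p = 0.0441) in granulocyte-monocyte progenitor-like and +1.14 (adjusted p = 0.182) in monocyte-like cells over 4 days, and +1.97 (adjusted p = 0.167) in dendritic-like cells over 3. Differences between classes were not tested.

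Genes higher with TCDD on days 14, 21 and 28 and not on day 7 numbered 20, NME2 and RNASEK among them. Of these, 11 (55%) overlap another gene on their strand, against 971 of 8299 genes of that level (11.7%) and 7 of 72 genes lower on the same days (9.72%), in line with a difference in how reads in overlapping genes were counted in these libraries, as a hypothesis. A different mix of cell classes is argued against as the whole cause, since 9 of the 20 (45%) were also higher on the 3 days within granulocyte-monocyte progenitor-like cells. Metallothionein genes need another explanation, as 0 of 4 overlap a gene on their strand, though paralogs may share reads. On day 28 MT2A in macrophage-like cells was at 34.0 CPM with vehicle and 757 with TCDD. These cells held 17091 of the TCDD library's 20117 MT2A counts. That day MT2A was not higher in monocyte-like (48.2 and 36.5) or dendritic-like cells (30.6 and 11.9), and intervals overlapped in both progenitor classes. On day 21 it was higher in monocyte-like (9.615 and 175.9) and dendritic-like cells (11.65 and 99.44) too. TCDD exposure of 14 days or more cannot be told apart from a library difference, since all 3 late TCDD libraries show it.

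B lineage and plasmacytoid dendritic markers were lower with TCDD on days 14, 21 and 28, with plasmacytoid dendritic-like cells fewer on all 3 days and B lineage-like cells on days 21 and 28 (on day 14 they were 3 cells with vehicle and 1 with TCDD). With all deposited barcodes counted, 26 markers summed to 1262 CPM with vehicle and 288 with TCDD on day 14, 1581 and 562 on day 21, and 1550 and 254 on day 28, and the highest ratio, 0.356, argues against the cell filter having removed such cells. That test replaced a first one on dropped barcodes, where the markers were at 264 CPM with TCDD (interval 210 to 329) and 207 with vehicle (interval 177 to 240) on day 14, 176 and 204 on day 21, and 41.3 and 240 on day 28. Depth per cell is argued against by 26 of 26 markers lower on the 3 days with every cell thinned. An effect of TCDD on lymphoid cells, the design's own explanation, and a difference in handling between the library sets cannot be told apart, since the 3 late TCDD libraries are all in the set with the difference.

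Other splits of the 8 cultured libraries into 4 and 4, of which 32 of 35 could be fitted, were compared with the real split. With the day block, splits that part the same days in the same way are 1 fit, which left 20 distinct splits, and these are too few for a share under 0.05. For genes at unadjusted p under 0.05 in the treatment effect the real split gave 2294 (1 of 20 as large, itself), and the highest other, 1975, set vehicle day 7 together with the TCDD libraries of days 14, 21 and 28. For lists the real value was 22 and the highest other 22 (2 splits as large), for HSPC-like cells 3 genes and 13 (3 splits), for granulocyte-monocyte progenitor-like cells 6 genes and 40 (4 splits), and for monocyte-like cells 1123 and 1363 (5 splits). Of the 8 splits that part all 4 days, 1 was as large for genes, 1 for lists (highest other 18) and 2 for each of these 3 classes. Splits that part only 2 days can hold the real contrast of TCDD and vehicle on those days. The other split with 22 lists held it on days 7 and 28. In monocyte-like cells the splits with 1310, 1317 and 1275 genes held it on days 14 and 21, 14 and 28, and 7 and 14. Such splits carry the treatment difference and do not measure chance. The split with 1363 genes in monocyte-like cells parts all 4 days and is the real split with vehicle and TCDD of day 21 swapped. Why it gave more genes than the real split was not tested. In both progenitor classes the highest other split was again the one that sets vehicle day 7 with the late TCDD libraries. A TCDD effect that differs between day 7 and later days, or a library difference, would each give this. The splits cannot tell them apart. For dendritic-like cells the real value was 1138 and the highest other 707 (1 of 7 distinct splits as large), and these splits too are too few.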
